A study of Homo sapiens with 12 samples.

How the data were processed

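Bulk RNA sequencing of H9 cells, a human embryonic stem cell line, was analysed for 12 libraries, 3 from each of 4 culture systems: 2D, static 3D, dynamic 3D and microspace fiber. Per the labels' protocols, the cells were grown in Essential 8 medium, harvested on day 3, and their total RNA was extracted on columns with DNase treatment. The libraries were made with TruSeq RNA v2 reagents and 12 samples shared a sequencing lane, per the labels' protocols. The authors deposited whole-number read counts per gene symbol for each library, with no normalization. Per the submitters' processing notes, Bowtie, HTSeq and the hg19 genome build were used. Their versions, the gene annotation, the strand setting of the counting and the handling of reads with several alignments are not given in the sources used here.

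Each deposited count table held 23368 gene rows and 5 summary rows. The summary rows were kept out of library sizes and tests. Reads assigned to no gene made up 12.45 to 13.78% of all rows per library and ambiguous reads 1.83 to 2.05%. The remaining 84.39 to 85.52% were gene counts, 9766887 to 14402616 per library. This library kit does not mark strand, so reads cannot be told apart where a gene overlaps an antisense gene. Such reads may have been set aside as ambiguous and counted for neither gene. Reads of near-identical family members, such as ribosomal protein genes with processed pseudogenes, histone genes, metallothioneins and IFITM genes, may have been assigned to a relative or dropped, and levels of single members of these families are uncertain. No coordinates are given because an hg19 annotation was not used here.

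Groups and replicate numbers were taken from the sample titles. Genes were kept with edgeR's filterByExpr for the 4 groups (minimum count 10, minimum total count 15), which left 15201 genes. Library sizes were scaled by TMM. Expression levels are in CPM, computed from TMM-scaled library sizes and given as mean ± SD over 3 libraries. Gene changes were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test, with all 12 libraries in one fit so that the 4 groups shared one estimate of the spread, for 6 pairwise comparisons. P-values were adjusted by Benjamini and Hochberg over the genes of each comparison, and genes were called at an adjusted p below 0.05 with no minimum fold. Standard errors (SE) belong to the log2 fold changes of the fit. Principal components and list levels per library used log2 CPM with a prior count of 2.

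Gene lists for cell states, other cell types, stress, metabolism, signalling, adhesion, cell cycle and RNA quality were written before the data were examined. They were 40 in all with 1111 distinct genes, of which 87 belong to more than 1 list. The RNA quality lists were cytosolic ribosomal proteins and replication-dependent histones. A list was tested where at least 5 members passed the filter, which held for 39 lists. Lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, a test that compares a list with all other genes, and adjusted over the lists of each comparison. The same test with a correlation estimated for each list, and fry, which tests whether a list moves one way without comparing it with other genes, were run as alternatives. Counts of changed members are given by the adjustment over all tested genes and, where stated, adjusted over the list alone.

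The genes named in the text follow a rule set before the data were examined. In each comparison it took the 6 called genes with the largest change each way, among those with a mean of at least 5 CPM in the higher group and no overlap between libraries of both groups, leaving out gene symbols of non-coding or unnamed loci. It also took up to 4 members of each called list with the smallest adjusted p, and a fixed set of marker genes whatever their values (POU5F1, NANOG, SOX2, LIN28A, T, SOX17, PAX6, GATA3, VEGFA, LDHA, CTGF, CYR61, CDKN1A, HMGCS1 and FOS). Up to 5 members that moved against the rest of a called list are also named; they were chosen after their values were seen, as were the genes named for a single system.

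Changes against 2D share the 2D libraries. Overlaps of calls were therefore set beside the number given by independent lists and beside 20 simulated sets of unchanged groups tested against simulated shared controls. Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, fits of the 2 compared groups alone, replicate number as a block, thinning of all libraries to the smallest, a 2-fold minimum, and leaving out each library in turn. Leaving dynamic 3D replicate 1 out of comparisons that do not hold it was added after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

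The tests were run on simulated counts for the 15201 genes with 200 genes changed. Of genes changed 1.5-fold, the share recovered was 75.4% for static 3D against 2D, 58.2% for dynamic 3D against 2D, 70.7% for fiber against 2D, 77.3% for fiber against static 3D, 73.5% for fiber against dynamic 3D and 66.2% for dynamic against static 3D. Of genes changed 2-fold, the shares were 84.9%, 80.3%, 87.5%, 86.4%, 87.3% and 82.9% in the same order. Unchanged genes made up 3.9%, 7.1%, 2.9%, 8.3%, 8.1% and 9.8% of the calls in that order. Each share came from a single draw, with 57 to 75 changed genes per fold and 5 to 18 unchanged genes called. Apart from the changed genes, all groups had the same mean and spread per gene, and no outlying library was simulated. Differences between comparisons therefore do not rank their power or error, and far fewer genes were changed than were called in the data.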

Results

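Transcript levels were measured by RNA sequencing in H9 human embryonic stem cells kept for 3 days in one medium in 4 culture systems: on a 2D surface, in static 3D suspension, in dynamic 3D suspension, and in a microspace system whose libraries are named for a fiber (called fiber here). Each system had 3 libraries. Gene counts per library ran from 9766887 (2D replicate 3) to 14402616 (fiber replicate 3), and 17637 to 18358 genes had at least 1 count. The labels number the replicates and do not say whether they came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

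The libraries of 2D, static 3D and fiber formed separate groups, with static 3D farthest from 2D, and those of dynamic 3D were more scattered. On the first principal component, which held 39.7% of the variance, static 3D libraries lay at 40.3 to 41.3, 2D libraries at -27.6 to -23.1, and fiber libraries at -21.63 to -19.98. Dynamic 3D replicate 1 lay at -14.7, apart from replicates 2 and 3 at 15.5 and 14.9. The biological coefficient of variation between dynamic 3D replicates 2 and 3 was 0.0366, and replicate 1 differed from them by 0.164 and 0.167. For the pairs of the other systems it was 0.0200 to 0.0453. Over all libraries of a system it was 0.1306 in dynamic 3D and 0.0274 to 0.0392 in the other systems. The main fit gives all systems one spread per gene, which these values go against. Its SEs and p-values therefore tend to be too small for comparisons with dynamic 3D and too large for the others. Between dynamic 3D replicates 1 and 2, 973 of 11843 genes differed by over 1.5-fold, against 17 of 11951 between replicates 2 and 3. Reads outside annotated genes made up 12.5 ± 0.081% of reads in 2D, 13.7 ± 0.078% in static 3D, 13.3 ± 0.487% in dynamic 3D and 12.7 ± 0.020% in fiber (n = 3). Within dynamic 3D this share was 12.78% in replicate 1, 13.71% in replicate 2 and 13.48% in replicate 3.

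**Figure D1:**
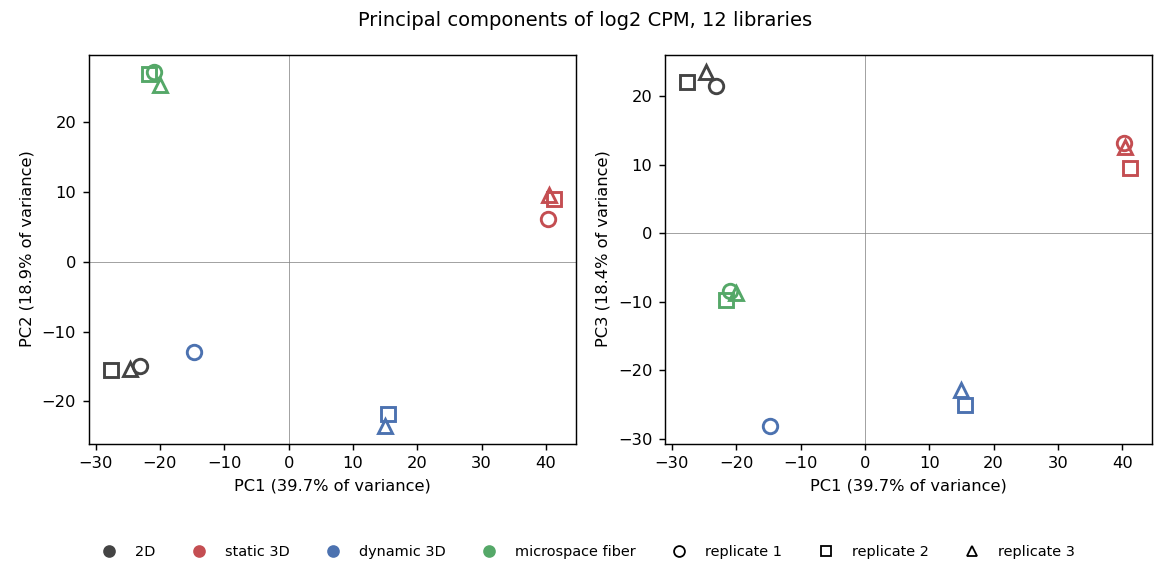
Principal components 1 and 2 (left) and 1 and 3 (right) of log2 CPM for the 12 libraries, with the share of variance on each axis, systems by colour and replicate numbers by marker shape. Dynamic 3D replicate 1 sits at -14.7 on component 1, and dynamic 3D replicates 2 and 3 sit at 15.5 and 14.9.

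The genes of the core pluripotency network were expressed at high levels in each system. POU5F1, which encodes the transcription factor OCT4, was at 1328 ± 33.8 CPM in 2D, 1123 ± 36.4 in static 3D, 1461 ± 90.8 in dynamic 3D and 1297 ± 32.9 in fiber (n = 3). NANOG was at 142 ± 3.94, 111 ± 2.01, 162 ± 11.2 and 169 ± 2.39 CPM in the same order, and SOX2 at 198 ± 18.2, 289 ± 4.85, 268 ± 15.5 and 242 ± 13.0. LIN28A, an RNA-binding protein that blocks let-7 maturation, was at 1745 ± 47.8 CPM in 2D, above the 1342 ± 15.3, 1088 ± 209 and 1428 ± 32.1 of the other systems. Against 2D, static 3D had less POU5F1 (log2 change -0.24, SE 0.050, adjusted p = 7.5e-04), less NANOG (-0.35, SE 0.054, adjusted p = 4.3e-05) and more SOX2 (0.55, SE 0.065, adjusted p = 3.6e-06). NANOG was higher than in 2D in fiber (0.26, SE 0.053, adjusted p = 1.3e-03). POU5F1 in fiber was within the spread of 2D (-0.03, SE 0.050, adjusted p = 0.63). For dynamic 3D against 2D, POU5F1 changed by 0.14 (SE 0.050, adjusted p = 0.034). That call was lost without any of the 3 2D libraries or dynamic 3D replicate 3 (adjusted p = 0.077 to 0.14). It was also lost with RLE size factors (adjusted p = 0.055), with DESeq2 (adjusted p = 0.052) and in a fit of the 2 groups (adjusted p = 0.11).

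Markers of differentiated lineages among the fixed genes were low. T, a primitive streak factor, was at 0.515 ± 0.208 to 0.824 ± 0.311 CPM across the systems and PAX6, a neuroectoderm factor, at 1.08 ± 0.463 to 1.75 ± 0.516 (n = 3), with no call for either gene in any of the 6 comparisons. In a fit of fiber and 2D alone, PAX6 was called (0.74, adjusted p = 0.048). SOX17, an endoderm factor, had 0 counts in each of the 12 libraries, where 3 counts would be 0.208 to 0.307 CPM, a limit that covers counting error only. GATA3, a trophoblast and amnion factor, had 35 counts in all and at most 6 in a library, and did not pass the filter.

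Between 5758 and 8419 of 15201 genes were called in each comparison. Static 3D had the most against 2D (4247 higher and 4172 lower), followed by dynamic 3D (3768 and 3232) and fiber (2964 and 2794). In fits of the 2 compared groups alone, fiber (7858) had more than dynamic 3D (5269), so the order of these 2 depends on the fit. With a change of at least 2-fold as well, static 3D had 1026 genes higher and 160 lower than 2D, dynamic 3D 559 and 175, and fiber 328 and 218. Among the 3D systems, 7723 genes were called for fiber against static 3D (3841 higher, 3882 lower), 5898 for fiber against dynamic 3D (2848 and 3050) and 6306 for dynamic against static 3D (3262 and 3044). The larger side turned with another scaling for static 3D and fiber against 2D (4214 and 4253, 2889 and 2899, both with RLE) and for dynamic against static 3D (2913 and 3305 with upper quartile). The share called higher in dynamic 3D against 2D was 53.8%, and 51.3% to 63.4% with other scalings. The 3 libraries of one group did not overlap those of the other for 66.2% of genes in static 3D against 2D, 48.7% in dynamic 3D against 2D and 57.4% in fiber against 2D. Among the 3D systems the shares were 64.5%, 44.1% and 47.0%, where chance gives 10% for 3 against 3.

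**Figure D2:**
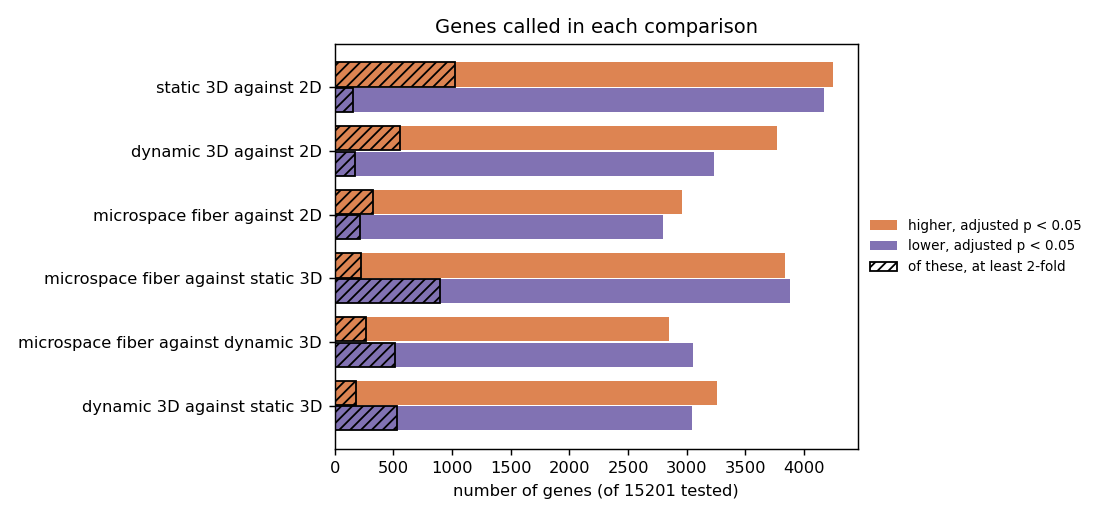
Number of genes (horizontal axis, of 15201 tested) called higher (orange) or lower (purple) in each of the 6 comparisons at an adjusted p below 0.05, with the hatched part changed at least 2-fold. Static 3D against 2D had 1026 genes at least 2-fold higher and 160 at least 2-fold lower.

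Static 3D was compared with 2D to see how cells in unstirred suspension differ from cells on a surface. Static 3D cells had far higher levels of genes induced by low oxygen. DDIT4, an inhibitor of mTORC1 induced by hypoxia, stood at 983 ± 19.0 CPM against 17.9 ± 2.99 in 2D (n = 3, log2 change 5.78, SE 0.099, adjusted p = 2.4e-16), and VEGFA, the angiogenic growth factor, at 135 ± 9.02 against 37.3 ± 2.47 (1.85, SE 0.097, adjusted p = 5.9e-10). The glucose transporter gene SLC2A1 rose as well (1074 ± 71.0 against 233 ± 6.01 CPM), and the chaperone gene HSPA8 fell (1401 ± 20.1 against 2839 ± 26.0).

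Of 39 hypoxia-induced genes, 36 rose and 1 fell (AK4), or 37 and 1 adjusted over the list alone, with a median log2 change of 1.85 (camera adjusted p = 1.1e-22, and adjusted p = 0.015 with an estimated correlation). Among them BHLHE40, a transcriptional repressor, rose by 4.94 (SE 0.085, adjusted p = 2.4e-16), PFKFB4 by 2.69 (SE 0.064) and the histone demethylase KDM3A by 2.08 (SE 0.061). NDRG1 also rose (29.2 ± 8.68 against 1.68 ± 0.300 CPM, log2 change 4.12, SE 0.240). Of 22 glycolysis genes, 14 rose and 3 fell (HK1, LDHB and SLC16A1), counts that were equal adjusted over the list alone (camera adjusted p = 8.5e-04, and adjusted p = 0.47 with an estimated correlation). SLC2A1 rose by 2.21 (SE 0.150, adjusted p = 1.1e-08), PGK1 doubled (1.03, SE 0.049) and LDHA, which makes lactate, rose by 0.50 (SE 0.058). Of 74 nuclear-encoded oxidative phosphorylation genes, 54 fell (55 adjusted over the list alone) and 2 rose (NDUFB4 and NDUFV2), with a median of -0.27 (camera adjusted p = 2.0e-09, and adjusted p = 0.15 with an estimated correlation). UQCRFS1 fell by 0.67 (SE 0.066) and SDHD fell by 0.55 (SE 0.056).

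Protein-folding genes were lower in static 3D than in 2D. Of 25 genes of the unfolded protein response of the endoplasmic reticulum, 19 fell and 2 rose (DNAJB9 and EDEM1) (camera adjusted p = 4.2e-07, and adjusted p = 0.015 with an estimated correlation). XBP1, a transcription factor of that response, went from 128 ± 1.45 to 48.9 ± 1.17 CPM (-1.38, SE 0.049, adjusted p = 5.2e-12) and the chaperone HSPA5 from 990 ± 2.21 to 593 ± 23.8 (-0.74, SE 0.044). Of 20 cytosolic heat shock genes, 14 fell and 1 rose (DNAJB4) (camera adjusted p = 7.6e-07, and adjusted p = 0.015 with an estimated correlation), with HSPA8 at -1.02 (SE 0.066) and DNAJA1 at -1.04 (SE 0.075). Amino acid response genes, which include ATF4 targets, fell in 25 of 35 cases (camera adjusted p = 6.9e-06, and adjusted p = 0.14 with an estimated correlation). SLC7A5, a transporter of large neutral amino acids, fell by 1.54 (SE 0.090). The 4 members that rose were DDIT4, DDIT3, STC2 and VLDLR, and DDIT4 and STC2 are also on the hypoxia list. Of 25 cholesterol biosynthesis genes, 18 fell and 4 rose (MSMO1, SC5DL, SREBF2 and STARD4) (camera adjusted p = 5.4e-03, and adjusted p = 0.64 with an estimated correlation). The counts of these 4 lists were equal adjusted over the list alone.

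S-phase genes fell in 42 of 46 cases, and RAD51AP1 and ATAD2 rose, counts that were equal adjusted over the list alone (camera adjusted p = 2.1e-11, and adjusted p = 0.29 with an estimated correlation). The replication licensing factors MCM6 and CDC6 fell by 0.55 (SE 0.046) and 0.72 (SE 0.066) on the log2 scale. Cytosolic ribosomal protein genes fell in 59 of 75 cases, or 62 adjusted over the list alone, and none rose, with a median of -0.22 (camera adjusted p = 3.6e-11, and adjusted p = 0.32 with an estimated correlation). RPS26 fell by 0.83 (SE 0.090) and RPL5 fell by 0.31 (SE 0.048). Among the largest changes, the neural transcription factor gene OLIG3 rose from 1.69 ± 0.210 to 29.3 ± 3.87 CPM (4.10, SE 0.572, adjusted p = 1.9e-05) and NOG, which encodes the BMP antagonist noggin, from 0.375 ± 0.067 to 6.39 ± 2.01 (4.04, SE 0.338). LEFTY1 and LEFTY2, inhibitors of NODAL signalling, fell by 2.24 (SE 0.389) and 2.05 (SE 0.314), the BMP target ID3 fell by 1.64 (SE 0.244), and HMX2, LRFN5 and EBF2 fell by 2.10 (SE 0.210), 2.17 (SE 0.296) and 1.73 (SE 0.338). Among the fixed markers, CDKN1A rose (1.03, SE 0.273, adjusted p = 4.5e-03) and HMGCS1 fell (-0.31, SE 0.095, adjusted p = 0.011). CTGF, a YAP target, was at 21.7 ± 1.96 against 35.3 ± 0.469 CPM in 2D (-0.70, SE 0.251, adjusted p = 0.026). The CTGF call was lost without any of the 6 libraries compared (adjusted p = 0.057 to 0.096) and with DESeq2 (adjusted p = 0.27), and that of HMGCS1 without static 3D replicate 1 (adjusted p = 0.052). Without dynamic 3D replicate 1, which is in neither group but shares the fit, CTGF kept its call (-0.70, adjusted p = 5.5e-10). CYR61 (-0.57, adjusted p = 0.12) and FOS (0.66, adjusted p = 0.16) were not called, and both were called without dynamic 3D replicate 1 (-0.57, adjusted p = 3.4e-12, and 0.66, adjusted p = 1.3e-11).

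**Figure D3:**
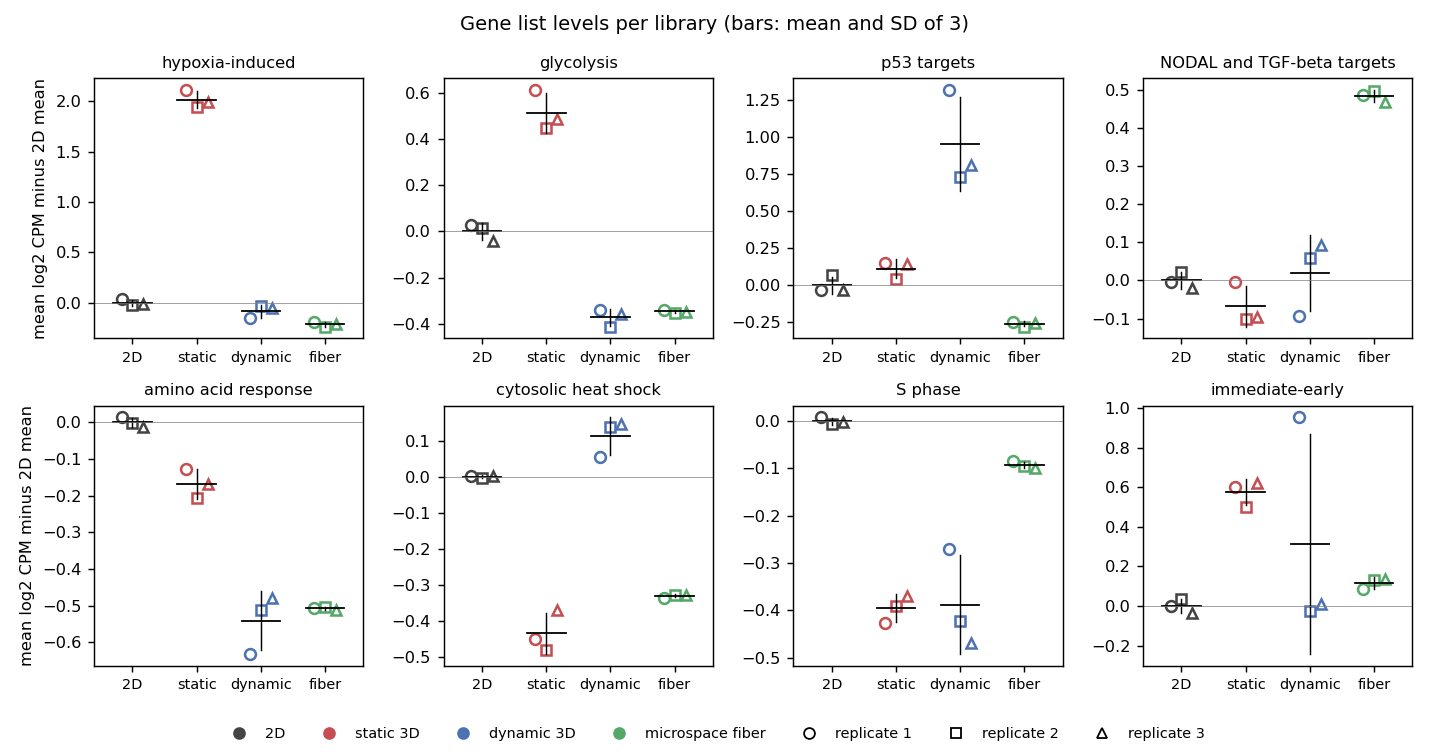
Level of 8 gene lists per library, as the mean log2 CPM of members minus the mean of the 2D libraries (vertical axis), with systems by colour, replicates by marker shape, and the mean and SD of 3 libraries as lines. Hypoxia-induced genes lie near 2 in static 3D, and dynamic 3D replicate 1 lies above replicates 2 and 3 for p53 targets and immediate-early genes.

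Dynamic 3D was compared with 2D to see how cells in moving suspension differ from cells on a surface. The stress cytokine gene GDF15 was higher in dynamic 3D (10.96 ± 5.07 against 0.503 ± 0.221 CPM, n = 3, log2 change 4.41, SE 0.446, adjusted p = 1.7e-06). So was the cell cycle inhibitor CDKN1A, a target of the tumour suppressor p53 (34.2 ± 13.4 against 5.28 ± 0.791 CPM, 2.68, SE 0.247, adjusted p = 8.5e-07). CTGF fell to 3.88 ± 3.70 from 35.3 ± 0.469 CPM (-3.20, SE 0.316, adjusted p = 1.5e-06). RBM3, a cold-induced RNA-binding protein, fell to 59.2 ± 12.1 from 311 ± 5.87 CPM (-2.40, SE 0.091, adjusted p = 1.6e-10). Of 11 lists called against 2D, 0 were called with an estimated correlation.

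Of 30 p53 targets, 25 rose and 1 fell (PMAIP1), or 26 and 1 adjusted over the list alone (camera adjusted p = 4.4e-10, and adjusted p = 0.37 with an estimated correlation). The death receptor gene TNFRSF10B rose by 1.06 (SE 0.073), TP53INP1 by 1.23 (SE 0.090) and SESN1 by 1.11 (SE 0.107). The mean log2 level of the list relative to 2D was 1.313 in dynamic 3D replicate 1, 0.729 in replicate 2 and 0.812 in replicate 3. Without replicate 1, 24 members rose and 2 fell (camera adjusted p = 4.8e-09), and CDKN1A, at 49.3, 23.9 and 29.4 CPM in replicates 1 to 3, stood at 2.32 on the log2 scale. Several of the largest increases were set by replicate 1. EGR1, an immediate-early gene, was at 352, 28.3 and 25.2 CPM in replicates 1 to 3 (3.13, SE 0.753, adjusted p = 3.0e-03, and 0.80 without replicate 1). OLIG3 was at 22.6, 3.12 and 4.06 CPM (2.53, SE 0.642, and 1.08 without replicate 1), and VAT1L rose by 2.72 (SE 0.411, and 1.97 without replicate 1). PLA2G2A rose by 3.12 (SE 0.413). FOS was at 144, 29.2 and 34.1 CPM in replicates 1 to 3, with no call with replicate 1 (0.35, adjusted p = 0.50) and a lower level than in 2D without it (-0.77, adjusted p = 2.7e-10).

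Of 22 glycolysis genes, 16 fell (17 adjusted over the list alone) and 2 rose (ENO2 and ENO3) (camera adjusted p = 1.0e-07, and adjusted p = 0.18 with an estimated correlation), with LDHA at 287 ± 25.8 against 539 ± 12.1 CPM (-0.91, SE 0.059). Oxidative phosphorylation genes fell in 50 of 74 cases (52 adjusted over the list alone) and 2 rose (NDUFB4 and ATP5H) (camera adjusted p = 1.8e-11, and adjusted p = 0.090 with an estimated correlation), among them CYC1 (-0.72, SE 0.065). Of 25 cholesterol biosynthesis genes, 18 fell and 3 rose (PMVK, SC5DL and SREBF2) (camera adjusted p = 2.9e-06, and adjusted p = 0.37 with an estimated correlation). HMGCS1, an early enzyme of that pathway, was at 530 ± 103 against 1066 ± 17.1 CPM (-1.01, SE 0.096). The cholesterol list stood at -0.199 in replicate 1 and at -0.560 and -0.530 in replicates 2 and 3. Fatty acid synthesis genes fell in 13 of 17 cases (14 adjusted over the list alone) and none rose (camera adjusted p = 1.8e-07, and adjusted p = 0.090 with an estimated correlation), including SREBF1 (-0.84, SE 0.081) and SCD (-0.68, SE 0.077). Of 35 amino acid response genes, 24 fell and none rose (camera adjusted p = 1.1e-12, and adjusted p = 0.054 with an estimated correlation), with SLC7A5 at 71.5 ± 11.6 against 253 ± 2.72 CPM (-1.82, SE 0.092) and SHMT2 at -0.71 (SE 0.050). NRF2 oxidative stress genes fell in 14 of 22 cases and 4 rose (FTL, ABCC1, ABCC2 and TXNIP) (camera adjusted p = 6.4e-03, and adjusted p = 0.090 with an estimated correlation), with the cystine transporter SLC7A11 at -1.23 (SE 0.091). The NRF2 list stood at -0.232 in replicate 1 and at -0.067 and -0.115 in replicates 2 and 3. Of 6 genes on the metallothionein list, 5 fell (MT1E, MT1F, MT1G, MT1X and MT2A) and the zinc exporter gene SLC30A1 was not called (camera adjusted p = 5.0e-04, and adjusted p = 0.090 with an estimated correlation). MT1X fell by 1.46 (SE 0.105). The counts of the cholesterol, amino acid, NRF2 and metallothionein lists were equal adjusted over the list alone.

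S-phase genes fell in 39 of 46 cases and TYMS rose (camera adjusted p = 3.2e-14, and adjusted p = 0.16 with an estimated correlation), with MCM6 at -0.85 (SE 0.047). Ribosomal protein genes fell in 70 of 75 cases (72 adjusted over the list alone) and none rose, with a median of -0.31 (camera adjusted p = 1.0e-22, and adjusted p = 0.090 with an estimated correlation), with RPS7 at -0.46 (SE 0.045). Of 40 actin cytoskeleton and SRF target genes, 24 fell and 5 rose (ACTA2, ACTN1, TAGLN2, TPM4 and PDLIM5) (camera adjusted p = 9.3e-06, and adjusted p = 0.18 with an estimated correlation), with TPM3 at -0.53 (SE 0.042) and MYL9 at -1.21 (SE 0.145). The actin list stood at -0.153 in replicate 1 and at -0.303 and -0.292 in replicates 2 and 3. The S-phase and actin counts were equal adjusted over the list alone. TAGLN (1.81 ± 1.19 against 7.19 ± 1.66 CPM, adjusted p = 8.6e-05), CYR61 (-1.94, SE 0.326) and COL2A1 (-1.93, SE 0.191) were among the largest decreases. Without replicate 1, CTGF, CYR61 and TAGLN changed by -4.33, -2.96 and -2.67. Among the fixed markers, SOX2 rose (0.44, SE 0.065, adjusted p = 6.0e-05), LIN28A fell (-0.68, SE 0.088, adjusted p = 1.7e-05), NANOG rose (0.19, SE 0.053, adjusted p = 8.4e-03, adjusted p = 0.056 without 2D replicate 2 and 0.054 in a fit of the 2 groups) and VEGFA was not called (-0.12, SE 0.103, adjusted p = 0.36).

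Fiber was compared with 2D to see how cells in the microspace system differ from cells on a surface. The ligand gene NODAL was higher in fiber, at 85.1 ± 3.73 against 28.4 ± 1.62 CPM (n = 3, log2 change 1.58, SE 0.244, adjusted p = 1.1e-04), as was its target LEFTY2 at 39.9 ± 2.19 against 11.1 ± 0.698 (1.85, SE 0.226, adjusted p = 1.3e-05). The amino acid response and heat shock lists were lower than in 2D, each with an adjusted p of 0.019 with an estimated correlation. CTGF fell to 3.98 ± 0.888 from 35.3 ± 0.469 CPM (-3.15, SE 0.314, adjusted p = 1.8e-06).

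Of 19 NODAL and TGF-beta targets, 13 rose and 1 fell (FOXH1) (camera adjusted p = 2.8e-03, and adjusted p = 0.053 with an estimated correlation), including the SMAD corepressor gene SKIL (0.89, SE 0.046). Without dynamic 3D replicate 1, 13 rose and 4 fell. Of 13 primitive streak genes, 8 rose and none fell (camera adjusted p = 0.011, and adjusted p = 0.12 with an estimated correlation), with LHX1 at 5.68 ± 1.45 against 1.87 ± 0.269 CPM (adjusted p = 7.7e-05) and WNT3 at 9.56 ± 0.895 against 5.46 ± 0.371 (0.81, SE 0.161). Without 2D replicate 3, 5 rose (adjusted p = 0.030). NODAL belongs to both lists. The primitive streak list also shares 3 genes with the WNT targets, T and WNT3 among them. The mesoderm list shares 1 gene with the BMP targets. Of 10 mesoderm genes, 6 rose and 1 fell (PDGFRB) (camera adjusted p = 8.9e-03, and adjusted p = 0.068 with an estimated correlation). The receptor gene KDR doubled to 139 ± 2.96 CPM (1.01, SE 0.075), a level also reached in static 3D (146 ± 11.8) and dynamic 3D (152 ± 5.46), and PDGFRA rose by 1.51 (SE 0.222). Without the filter on low counts the mesoderm list had an adjusted p of 0.068. Of 14 naive-state genes, 5 rose (KLF4, DPPA3, SUSD2, TFAP2C and GDF3) and KLF17 fell (camera adjusted p = 0.016, and adjusted p = 0.079 with an estimated correlation), with KLF4 at 15.8 ± 1.71 against 5.13 ± 0.539 CPM (1.62, SE 0.124). The mean log2 level of the naive-state list relative to 2D was 0.520 to 0.630 in fiber, 0.565 to 0.686 in static 3D and 0.489 to 0.528 in dynamic 3D. WNT targets rose in 7 of 17 cases and 2 fell (NKD2 and ZNRF3) (camera adjusted p = 0.023, and adjusted p = 0.20 with an estimated correlation). Those that rose included AXIN2 (0.62, SE 0.068) and LGR5 (2.00, SE 0.333). The WNT list stood at 0.286 to 0.371 relative to 2D in fiber and at 0.238 to 0.332 in static 3D. In dynamic 3D replicates 1 to 3 it was at -0.043, 0.253 and 0.277. BMP targets rose in 8 of 14 cases and 2 fell (ID2 and ID3) (camera adjusted p = 0.024, and adjusted p = 0.098 with an estimated correlation), with GATA2 at 5.84 ± 0.392 against 1.44 ± 0.178 CPM (2.00, SE 0.193). The counts of these 6 lists were equal adjusted over the list alone.

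Of 35 amino acid response genes, 27 fell and SLC1A4 rose, or 31 and 2 adjusted over the list alone (camera adjusted p = 9.1e-14, and adjusted p = 0.019 with an estimated correlation). SLC7A5 fell to 53.2 ± 0.773 from 253 ± 2.72 CPM (-2.25, SE 0.094, adjusted p = 2.7e-10) and its partner SLC3A2 fell by 0.70 (SE 0.058). Of this list 3 genes rose without dynamic 3D replicate 1, as did 2 glycolysis genes. Glycolysis genes fell in 17 of 22 cases (19 adjusted over the list alone) and none rose (camera adjusted p = 1.6e-08, and adjusted p = 0.11 with an estimated correlation), with LDHA at -0.54 (SE 0.058) and HK1 at -0.70 (SE 0.084). Oxidative phosphorylation genes fell in 50 of 74 cases (53 adjusted over the list alone) and ATP5H rose (camera adjusted p = 5.7e-12, and adjusted p = 0.067 with an estimated correlation), with UQCRH at -0.40 (SE 0.049). Ribosomal protein genes fell in 69 of 75 cases (71 adjusted over the list alone) and none rose (camera adjusted p = 1.8e-21, and adjusted p = 0.075 with an estimated correlation), with RPS3 at -0.42 (SE 0.056). Of 39 hypoxia-induced genes, 14 fell (15 adjusted over the list alone) and 4 rose (PDK1, BHLHE40, GBE1 and WSB1) (camera adjusted p = 0.016, and adjusted p = 0.45 with an estimated correlation), with STC2 at -1.46 (SE 0.078) and VEGFA at -0.57 (SE 0.106). Fatty acid synthesis genes fell in 4 of 17 cases (FADS2, ELOVL1, ELOVL5 and ACSL3, equal adjusted over the list alone) (camera adjusted p = 0.034, and adjusted p = 0.41 with an estimated correlation). Without dynamic 3D replicate 1, 11 fell and 1 rose (adjusted p = 0.012). ELOVL1 (-0.32, adjusted p = 0.031) lost its call without 2D replicate 1 or 2 or any fiber library (adjusted p = 0.056 to 0.15).

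Heat shock genes fell in fiber in 14 of 20 cases and none rose, with equal counts adjusted over the list alone (camera adjusted p = 1.3e-07, and adjusted p = 0.019 with an estimated correlation), including HSP90AA1 (-0.48, SE 0.050) and FKBP4 (-0.68, SE 0.054). Of 25 genes of the unfolded protein response, 11 fell (13 adjusted over the list alone) and SEL1L rose (camera adjusted p = 1.7e-04, and adjusted p = 0.053 with an estimated correlation), with XBP1 at -0.47 (SE 0.047). NRF2 genes fell in 11 of 22 cases (13 adjusted over the list alone) and 3 rose (GCLC, ABCC2 and TXNIP) (camera adjusted p = 6.1e-03, and adjusted p = 0.059 with an estimated correlation), with NQO1 at -0.66 (SE 0.070). The p53 targets fell in 12 of 30 cases (15 adjusted over the list alone) and 6 rose (camera adjusted p = 0.020, and adjusted p = 0.75 with an estimated correlation), with CDKN1A at 1.93 ± 0.745 against 5.28 ± 0.791 CPM (-1.44, SE 0.363) and SESN2 at -0.84 (SE 0.097). By fry the p53 targets had an adjusted p of 0.15. Of 46 S-phase genes, 17 fell (18 adjusted over the list alone) and 5 rose (ATAD2, BLM, USP1, CLSPN and E2F8) (camera adjusted p = 0.013, adjusted p = 0.59 with an estimated correlation and 0.056 by fry). Actin cytoskeleton and SRF targets fell in 16 of 40 cases (17 adjusted over the list alone) and 6 rose (camera adjusted p = 0.034, and adjusted p = 0.49 with an estimated correlation), with MYL9 at -1.28 (SE 0.146). Of 20 interferon-stimulated genes, 6 fell and 2 rose (MX1 and IRF9), equal adjusted over the list alone (camera adjusted p = 0.040, adjusted p = 0.51 with an estimated correlation and 0.083 without the filter on low counts), with IFITM3 at -0.64 (SE 0.068).

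The largest increases in fiber against 2D were those of CREB5 (3.23, SE 0.204), VAT1L (2.95, SE 0.405), EBF2 (65.1 ± 4.32 against 8.504 ± 1.57 CPM, 2.93, SE 0.229), the phosphatase gene DUSP8 (2.66, SE 0.136), MXD1 (2.52, SE 0.170) and NPFFR2 (2.23, SE 0.232). After CTGF, the largest decreases were those of FAM65B (-2.93, SE 0.240), SLC7A5, LRFN5 (-2.11, SE 0.294), VEPH1 (-1.91, SE 0.202) and MAP2, a neuronal cytoskeleton gene (29.1 ± 1.43 to 8.24 ± 0.411 CPM, -1.82, SE 0.246). Among the fixed markers, CYR61 fell (-1.68, SE 0.319, adjusted p = 6.7e-04) and SOX2 rose (0.29, SE 0.065, adjusted p = 2.3e-03). LIN28A changed by -0.29 (SE 0.087, adjusted p = 0.016), a call lost without 2D replicate 2 (adjusted p = 0.055) or fiber replicate 2 (adjusted p = 0.061). The LIN28A call was kept without dynamic 3D replicate 1 (-0.29, adjusted p = 2.0e-10). HMGCS1 (0.10, adjusted p = 0.45, and 0.10, adjusted p = 0.038 without dynamic 3D replicate 1) and FOS (-0.14, adjusted p = 0.81) were not called.

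**Figure D4:**
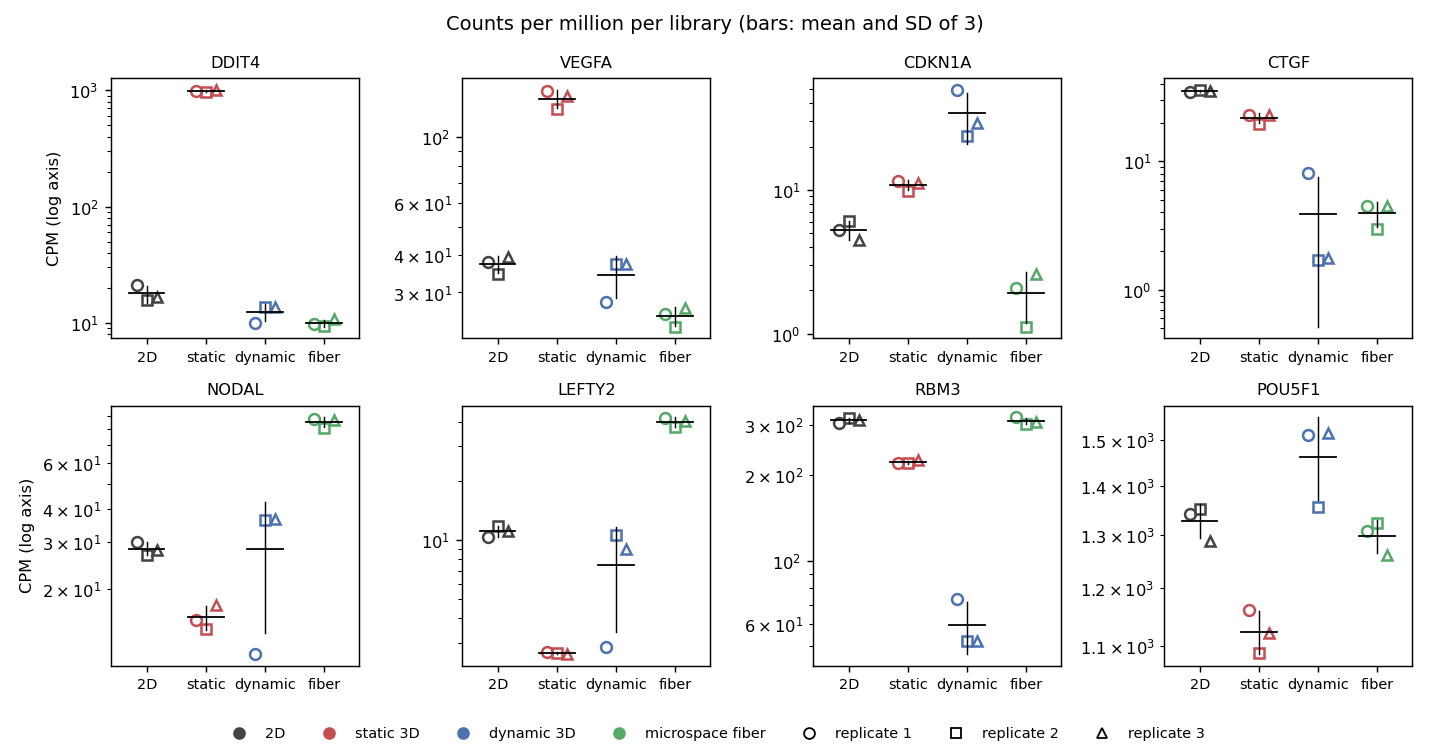
CPM per library on a log axis (vertical) for 8 genes in the 4 systems, with replicates by marker shape and the mean and SD of 3 libraries as lines. DDIT4 stands at 983 ± 19.0 CPM in static 3D against 17.9 ± 2.99 in 2D, and NODAL at 85.1 ± 3.73 CPM in fiber against 28.4 ± 1.62 in 2D.

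Fiber was set against static 3D to compare the microspace system with unstirred suspension. Hypoxia-induced genes were much lower in fiber, with DDIT4 at 9.93 ± 0.670 against 983 ± 19.0 CPM (n = 3, log2 change -6.62, SE 0.105, adjusted p = 1.1e-16) and VEGFA at 25.01 ± 1.86 against 135 ± 9.02 (-2.43, SE 0.099, adjusted p = 2.9e-11). LEFTY1, LEFTY2 and NODAL were higher in fiber: LEFTY1 was at 137 ± 6.13 against 11.7 ± 2.67 CPM (3.56, SE 0.375, adjusted p = 1.9e-06), LEFTY2 at 39.9 ± 2.19 against 2.67 ± 0.030 (3.89, SE 0.273) and NODAL at 85.1 ± 3.73 against 15.7 ± 1.66 (2.44, SE 0.256).

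Of 39 hypoxia-induced genes, 37 fell and AK4 rose, with a median of -2.01 (camera adjusted p = 1.5e-29, and adjusted p = 0.014 with an estimated correlation), among them BHLHE40 (-4.21, SE 0.077) and PFKFB4 (-3.13, SE 0.066). Glycolysis genes fell in 20 of 22 cases and LDHB rose (camera adjusted p = 3.2e-12, and adjusted p = 0.13 with an estimated correlation), with PGK1 at -1.41 (SE 0.050) and the lactate exporter SLC16A3 at -3.13 (SE 0.168). Of 19 NODAL and TGF-beta targets, 13 rose and 2 fell, BHLHE40 among them (camera adjusted p = 2.3e-03, and adjusted p = 0.085 with an estimated correlation), ID1 by 0.94 (SE 0.076). S-phase genes rose in 35 of 46 cases (38 adjusted over the list alone) and ATAD2 fell (camera adjusted p = 1.3e-08, and adjusted p = 0.42 with an estimated correlation), with RRM2 at 0.62 (SE 0.070). FGF and ERK feedback genes rose in 11 of 20 cases and 2 fell (PHLDA1 and FGFR1) (camera adjusted p = 0.027, and adjusted p = 0.60 with an estimated correlation), with CCND1 at 555 ± 6.58 against 337 ± 7.98 CPM (0.72, SE 0.048) and the feedback inhibitor SPRY4 at 1.06 (SE 0.105). Leaving out dynamic 3D replicate 1, 12 rose and 5 fell. Of 25 unfolded protein response genes, 16 rose and 2 fell (EDEM1 and ATF6) (camera adjusted p = 5.7e-04, and adjusted p = 0.087 with an estimated correlation), XBP1 by 0.91 (SE 0.049). Cholesterol biosynthesis genes rose in 15 of 25 cases and 3 fell (MSMO1, SC5DL and STARD4) (camera adjusted p = 0.022, and adjusted p = 0.60 with an estimated correlation), with MVK at 0.86 (SE 0.118).

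Of 47 extracellular matrix genes, 23 fell and 6 rose in fiber against static 3D (camera adjusted p = 0.014, and adjusted p = 0.60 with an estimated correlation), with COL11A1 at 10.1 ± 1.65 against 39.5 ± 2.52 CPM (-1.95, SE 0.141), the secreted protein SPP1 at -1.47 (SE 0.118) and the perlecan gene HSPG2 at -1.03 (SE 0.089). Interferon-stimulated genes fell in 11 of 20 cases and IFIT3 rose (camera adjusted p = 0.014, and adjusted p = 0.57 with an estimated correlation), with BST2 at -2.34 (SE 0.301). Apart from the S-phase list, the counts of the lists in this comparison were equal adjusted over the list alone. EBF2 (4.66, SE 0.269), the growth factor gene FGF8 (9.89 ± 0.688 against 0.887 ± 0.259 CPM, 3.47, SE 0.355) and GATA2 (3.04, SE 0.213) were among the largest increases and PPFIA4 (-4.57, SE 0.220) among the largest decreases. POU5F1 (0.21, SE 0.050, adjusted p = 2.8e-03) and NANOG (0.61, SE 0.053, adjusted p = 2.7e-07) were higher in fiber, and SOX2 (-0.26, SE 0.064), CTGF (-2.44, SE 0.322), CYR61 (-1.11, SE 0.321) and CDKN1A (-2.47, SE 0.317) were lower. With DESeq2 the CYR61 call was lost (adjusted p = 0.056). FOS (-0.80, adjusted p = 0.095) and LIN28A (0.09, adjusted p = 0.41) were not called, and both were called without dynamic 3D replicate 1 (-0.80, adjusted p = 3.8e-14, and 0.09, adjusted p = 0.011).

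Fiber was set against dynamic 3D to compare the microspace system with moving suspension. CDKN1A was lower in fiber, at 1.93 ± 0.745 against 34.2 ± 13.4 CPM (n = 3, log2 change -4.12, SE 0.283, adjusted p = 4.8e-08). So were GDF15 at 0.531 ± 0.119 against 10.96 ± 5.07 (-4.35, SE 0.423) and TNFRSF10B at 72.1 ± 1.03 against 236 ± 28.7 (-1.71, SE 0.075). HMGCS1 was higher in fiber, at 1139 ± 25.5 against 530 ± 103 CPM (1.10, SE 0.096, adjusted p = 5.6e-07). LEFTY2 was higher too, at 39.9 ± 2.19 against 7.503 ± 4.11 CPM (2.40, SE 0.232).

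Of 30 p53 targets, 25 fell (27 adjusted over the list alone) and PMAIP1 rose (camera adjusted p = 2.7e-15, and adjusted p = 0.29 with an estimated correlation), with BAX at -1.17 (SE 0.086) and DDB2 at -1.23 (SE 0.077). Without dynamic 3D replicate 1, where this list was highest, 25 fell and 2 rose (camera adjusted p = 2.1e-13). Cholesterol biosynthesis genes rose in 17 of 25 cases and PMVK fell (camera adjusted p = 2.0e-05, and adjusted p = 0.42 with an estimated correlation), and fatty acid synthesis genes rose in 11 of 17 cases with none lower (camera adjusted p = 9.7e-05, and adjusted p = 0.16 with an estimated correlation), SCD by 0.63 (SE 0.077). The cholesterol list stood at -0.199 relative to 2D in dynamic 3D replicate 1, at -0.560 and -0.530 in replicates 2 and 3, and at -0.066 to -0.041 in fiber. Of 19 NODAL and TGF-beta targets, 9 rose (10 adjusted over the list alone) and none fell (camera adjusted p = 0.012, and adjusted p = 0.13 with an estimated correlation), NODAL by 1.59 (SE 0.239). Leaving out dynamic 3D replicate 1, 14 rose (adjusted p = 1.6e-04). In dynamic 3D replicates 1 to 3, NODAL was at 11.4, 36.6 and 36.7 CPM and LEFTY1 at 10.02, 52.9 and 56.2. Of 16 definitive endoderm genes, 8 rose and PRDM1 fell (camera adjusted p = 0.017, and adjusted p = 0.13 with an estimated correlation). They included FOXA2 (7.82 ± 0.652 against 1.99 ± 0.387 CPM, 1.98, SE 0.187), CYP26A1, which degrades retinoic acid (1.69, SE 0.177), and LEFTY1 (1.78, SE 0.324). All 6 members of the metallothionein list rose (camera adjusted p = 7.0e-04, and adjusted p = 0.13 with an estimated correlation), with MT1X at 15.8 ± 0.760 against 7.87 ± 0.991 CPM.

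S-phase genes rose in 29 of 46 cases (33 adjusted over the list alone) in fiber against dynamic 3D and HELLS fell (camera adjusted p = 4.1e-10, and adjusted p = 0.29 with an estimated correlation), with MCM6 at 0.64 (SE 0.047). Actin cytoskeleton and SRF targets rose in 18 of 40 cases (19 adjusted over the list alone) and 5 fell (ACTA2, ACTN1, FHL1, PDLIM5 and MSN) (camera adjusted p = 9.4e-03, and adjusted p = 0.42 with an estimated correlation), with CALD1 at 0.46 (SE 0.042). The actin difference came from dynamic 3D replicates 2 and 3 (-0.303 and -0.292 relative to 2D), while replicate 1 (-0.153) lay at the level of fiber (-0.160 to -0.128). Heat shock genes fell in 15 of 20 cases and none rose (camera adjusted p = 1.8e-07, and adjusted p = 0.029 with an estimated correlation), with FKBP4 at -0.77 (SE 0.054) and HSP90AA1 by -0.55 (SE 0.050). Unfolded protein response genes fell in 14 of 25 cases and SEC61B rose (camera adjusted p = 8.8e-05, and adjusted p = 0.078 with an estimated correlation), with PDIA4 at -0.54 (SE 0.047). Of 20 interferon-stimulated genes, 14 fell and 2 rose (IFIT3 and MX1) (camera adjusted p = 2.7e-03, and adjusted p = 0.42 with an estimated correlation), with IFITM3 at -0.59 (SE 0.068). The interferon list was likewise at 0.208 and 0.293 in dynamic 3D replicates 2 and 3, and at -0.136 in replicate 1, near fiber (-0.318 to -0.165). Counts of the lists for this comparison were equal adjusted over the list alone where no second count is given, except that HELLS and 1 more S-phase gene fell (2 in all). EBF2 (4.73, SE 0.272), PDE1B (2.85, SE 0.264) and GATA2 (2.50, SE 0.198) were among the largest increases, with LGR5 (2.51, SE 0.342). LGR5 was low in dynamic 3D (0.948 ± 0.727 CPM), and its change was 2.07 without dynamic 3D replicate 1 and 3.26 without replicate 3. DOC2A (-2.63, SE 0.329), RFTN2 (-2.54, SE 0.286), FOSL1 (-3.03, SE 0.450) and BTG2 (-2.62, SE 0.389) were among the largest decreases, the last pair at -2.27 and -1.97 without dynamic 3D replicate 1.

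Markers that differed by library stood out in this comparison. CTGF (0.06, adjusted p = 0.93) and CYR61 (0.27, adjusted p = 0.57) were not called for fiber against dynamic 3D, and without dynamic 3D replicate 1 both were higher in fiber (1.19, adjusted p = 3.8e-05, and 1.28, adjusted p = 4.8e-15). FOS was not called (-0.49, adjusted p = 0.34) and was higher in fiber without that library (0.63, adjusted p = 3.5e-08). LDHA (0.38, SE 0.059, adjusted p = 1.3e-04) and LIN28A (0.39, SE 0.088, adjusted p = 2.4e-03) were higher in fiber and VEGFA was lower (-0.45, SE 0.105, adjusted p = 3.0e-03). POU5F1 was at -0.17 (SE 0.050, adjusted p = 0.013), a call lost without dynamic 3D replicate 3 (adjusted p = 0.054) or fiber replicate 3 (adjusted p = 0.068) and in a fit of the 2 groups (adjusted p = 0.062). NANOG (0.07, adjusted p = 0.33) and SOX2 (-0.15, adjusted p = 0.081) were not called. Without dynamic 3D replicate 1 they were (0.11, adjusted p = 0.040, and -0.14, adjusted p = 0.024), and SOX2 also without dynamic 3D replicate 3 (-0.19, adjusted p = 0.041).

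Dynamic 3D was set against static 3D to compare moving with unstirred suspension. Hypoxia-induced genes were much lower in dynamic 3D, DDIT4 at 12.4 ± 2.15 against 983 ± 19.0 CPM (n = 3, log2 change -6.30, SE 0.102, adjusted p = 1.6e-16), VEGFA at 34.3 ± 5.48 against 135 ± 9.02 (-1.97, SE 0.096). LDHA was lower at 287 ± 25.8 against 762 ± 37.1 (-1.41, SE 0.059). Protein-folding genes were higher in dynamic 3D, DNAJA1 at 362 ± 52.1 against 148 ± 5.57 CPM (1.29, SE 0.075). BAX, a pro-apoptotic gene, was at 128 ± 17.5 against 56.6 ± 5.40 (1.18, SE 0.086).

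Of 39 hypoxia-induced genes, 36 fell and JMJD6 rose, with a median of -1.88 (camera adjusted p = 7.3e-32, and adjusted p = 3.7e-03 with an estimated correlation), among them EGLN1, an oxygen sensor (-1.92, SE 0.059). Glycolysis genes fell in 17 of 22 cases and ENO3 rose (camera adjusted p = 1.2e-12, and adjusted p = 0.12 with an estimated correlation), with PGK1 at -1.46 (SE 0.050). Heat shock genes rose in 16 of 20 cases and none fell (camera adjusted p = 1.0e-10, and adjusted p = 3.7e-03 with an estimated correlation), HSPH1 by 1.03 (SE 0.049). Unfolded protein response genes rose in 19 of 25 cases and EDEM1 fell (camera adjusted p = 1.5e-10, and adjusted p = 3.7e-03 with an estimated correlation), XBP1 by 0.99 (SE 0.049) and MANF by 0.86 (SE 0.059). Of 30 p53 targets, 27 rose and none fell (camera adjusted p = 5.7e-12, and adjusted p = 0.33 with an estimated correlation), PHLDA3 by 1.99 (SE 0.188) and TNFRSF10B by 0.90 (SE 0.072). Without dynamic 3D replicate 1 the same numbers rose and fell (camera adjusted p = 1.9e-13), with a median of 0.58 in place of 0.76. Fatty acid synthesis genes fell in 10 of 17 cases and FADS1 rose (camera adjusted p = 4.7e-03, and adjusted p = 0.33 with an estimated correlation), with ACSS2 at -1.10 (SE 0.080). The counts of these 6 lists were equal adjusted over the list alone.

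Of 40 actin cytoskeleton and SRF targets, 19 fell (20 adjusted over the list alone) and 2 rose (ACTA2 and ACTN1) (camera adjusted p = 7.8e-04, and adjusted p = 0.33 with an estimated correlation), with VCL at -0.57 (SE 0.061). The actin list stood at -0.153 relative to 2D in dynamic 3D replicate 1, at -0.303 and -0.292 in replicates 2 and 3, and at -0.110 to -0.025 in static 3D. YAP/TAZ targets fell in 11 of 22 cases and 2 rose (FJX1 and AMOTL1, 3 adjusted over the list alone) (camera adjusted p = 0.013, and adjusted p = 0.13 with an estimated correlation). The YAP/TAZ list was at -0.143 in replicate 1, at -0.454 and -0.409 in replicates 2 and 3, and at 0.078 to 0.106 in static 3D. CTGF was at 3.88 ± 3.70 against 21.7 ± 1.96 CPM (-2.50, SE 0.324, and -3.63 without dynamic 3D replicate 1). CYR61 changed by -1.38 (SE 0.328, and -2.39 without that library). Mesenchymal transition genes fell in 6 of 18 cases and 2 rose (FN1 and MMP2) (camera adjusted p = 0.043, and adjusted p = 0.37 with an estimated correlation), with VIM at 22.9 ± 1.98 against 95.6 ± 20.1 CPM (-2.06, SE 0.119). Without dynamic 3D replicate 1, 10 fell (adjusted p = 0.034). The list was at 0.203 in that replicate, -0.137 and -0.117 in the others, and 0.420 to 0.548 in static 3D. That list lost its call without replicate 2 (adjusted p = 0.068) or 3 (adjusted p = 0.083). Immediate-early genes fell in 13 of 26 cases and 6 rose (camera adjusted p = 0.035, and adjusted p = 0.69 with an estimated correlation), with JUN at -1.71 (SE 0.187). This list stood at 0.953 relative to 2D in dynamic 3D replicate 1 and at -0.024 and 0.011 in replicates 2 and 3. Its call was lost without replicate 2 (adjusted p = 0.12), without replicate 3 (adjusted p = 0.13) and with the replicate number as a block (adjusted p = 0.059). FGF and ERK feedback genes rose in 12 of 20 cases and 3 fell (PHLDA1, IER3 and MYC) (camera adjusted p = 0.028, and adjusted p = 0.69 with an estimated correlation), with SPRY4 at 385, 268 and 281 CPM in dynamic 3D replicates 1 to 3 (0.87, SE 0.105). That list stood at 0.734 in replicate 1 and at 0.113 and 0.147 in replicates 2 and 3, and without replicate 1 had an adjusted p of 0.11.

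Ribosomal protein genes fell in 27 of 75 cases and RPS19 rose in dynamic against static 3D (camera adjusted p = 1.5e-03, and adjusted p = 0.67 with an estimated correlation), with RPL14 at -0.25 (SE 0.050). Without static 3D replicate 1, 13 fell (adjusted p = 0.014). Of the metallothioneins, 4 fell (MT1E, MT1G, MT1X and MT2A), or 5 adjusted over the list alone (camera adjusted p = 0.049, and adjusted p = 0.33 with an estimated correlation), with MT1X at -1.08 (SE 0.106). The MT2A call was lost without static 3D replicate 1 or 2 or dynamic 3D replicate 2 or 3 (adjusted p = 0.0504 to 0.12). It was also lost with no filter on low counts (adjusted p = 0.054), with DESeq2 (adjusted p = 0.073) and in a fit of the 2 groups (adjusted p = 0.089). That of MT1G was lost without static 3D replicate 1 or 3 or dynamic 3D replicate 3 (adjusted p = 0.055 to 0.093). Without static 3D replicate 1 or dynamic 3D replicate 3, 2 fell. The list lost its call without static 3D replicate 1 (adjusted p = 0.080), without any dynamic 3D library (adjusted p = 0.061 to 0.082) and in a fit of these 2 groups alone (adjusted p = 0.070). Apart from the actin, YAP/TAZ and metallothionein lists, counts were equal adjusted over the list alone. HMX2 (2.44, SE 0.200), SPATA18 (2.40, SE 0.247) and FAS (2.08, SE 0.324) were among the largest increases. FOSL1 (2.42, SE 0.415, and 1.65 without dynamic 3D replicate 1) and NHLH2 (1.81, SE 0.311, and 1.19 without it) were also among them. IGFBP5 (2.21 ± 0.786 against 31.2 ± 3.32 CPM, -3.80, SE 0.177), NOG (-3.81, SE 0.312) and APLN (-4.41, SE 0.329, and -5.22 without dynamic 3D replicate 1) were among the largest decreases. POU5F1 (0.38, SE 0.050, adjusted p = 2.5e-05) and NANOG (0.54, SE 0.053, adjusted p = 1.0e-06) were higher in dynamic 3D. LIN28A was lower (-0.30, SE 0.088, adjusted p = 0.011), a call lost without dynamic 3D replicate 2 or 3 (adjusted p = 0.055 and 0.054) or in a fit of the 2 groups (adjusted p = 0.069). FOS was not called (-0.31, adjusted p = 0.54) and was lower without dynamic 3D replicate 1 (-1.43, adjusted p = 2.5e-19).

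Many changes against 2D went the same way in more than 1 system. Static and dynamic 3D shared 2390 genes called higher and 2230 called lower than 2D, with 328 called in opposite directions. Static 3D and fiber shared 1763 higher and 1654 lower, with 444 opposite, and dynamic 3D and fiber 1707 higher and 1505 lower, with 304 opposite. Independent lists of these sizes would share 1940, 1595 and 1329 genes in one direction. In 20 simulated sets of unchanged groups against shared controls, at most 0, 0 and 1 genes were shared. Unchanged groups yield hardly any calls, so these counts are no yardstick for sharing between lists of the real sizes. In all 3 systems 1305 genes were higher and 1170 lower than in 2D, DUSP8 and CREB5 among the former and SLC7A5 and LRFN5 among the latter. Across genes, which are not independent replicates, the fold changes against 2D of static and dynamic 3D correlated at 0.606 (simulated 0.529), of static 3D and fiber at 0.411 (simulated 0.533) and of dynamic 3D and fiber at 0.465 (simulated 0.532). Their covariances were 0.179, 0.112 and 0.104 against simulated values of 0.0222, 0.0224 and 0.0224, differences of 0.157, 0.0893 and 0.0814. Genes with one sign in both changes made up 74.3%, 66.9% and 70.0%, where simulated unchanged groups gave 67.4%. The 3 2D libraries cannot be split into parts of at least 2, and part of the excess may come from the shared controls. The simulated correlations and shares of one sign follow from unchanged groups having the same controls. They are no yardstick for data with as many called changes as these. Values below them therefore do not show a lack of sharing.

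Other lists were not called in any of the 6 comparisons. These were primed pluripotency (smallest camera adjusted p = 0.17), neuroectoderm (0.33), neural crest (0.28), trophoblast and amnion (0.48), fibroblast and stroma (0.28), endothelial and blood (0.12), integrins and focal adhesion (0.53), epithelial junctions (0.23), Notch targets (0.10), NF-kappaB inflammation (0.18), G2 and M phase (0.051) and replication-dependent histones (0.061). Of 36 primed pluripotency genes, 7 rose and 14 fell in static 3D against 2D, 14 rose (15 adjusted over the list alone) and 7 fell in dynamic 3D, and 11 rose (12 adjusted over the list alone) and 10 fell in fiber. Without dynamic 3D replicate 1, 9 rose and 19 fell in static 3D, 15 and 13 in dynamic 3D, and 14 and 14 in fiber. The list stood at 0.113 relative to 2D in that replicate and at -0.053 and -0.054 in dynamic 3D replicates 2 and 3. Of 22 histone genes, 10 rose and 3 fell in dynamic 3D against 2D, and their mean log2 level was 0.796 in dynamic 3D replicate 1, 0.261 in replicate 2 and 0.220 in replicate 3. Without replicate 1, 5 of 23 histone genes rose and 4 fell (camera adjusted p = 0.61). The primitive streak list, called for fiber against 2D alone, stood at -0.299 in dynamic 3D replicate 1 and at 0.281 and 0.299 in replicates 2 and 3.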

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

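Leaving dynamic 3D replicate 1 out of comparisons that do not hold it was chosen after seeing the data. The numbers of called genes stayed within 1.5 times their value with RLE size factors, no filter on low counts, replicate number as a block, fits of the 2 groups alone, thinned libraries and DESeq2, and no called gene was called the other way. DESeq2 gave 7814, 6341, 5254, 6972, 5324 and 5587 genes for static 3D, dynamic 3D and fiber against 2D, fiber against static 3D, fiber against dynamic 3D and dynamic against static 3D. Replicate number as a block gave 8249, 6761, 5546, 7524, 5690 and 6091. Of these, fits of the 2 groups alone moved the numbers most, to 9547, 5269, 7858, 9273, 4184 and 4430, with fiber above dynamic 3D against 2D. The numbers fell in each comparison with dynamic 3D, the system with the largest spread, and rose in the others. A change of at least 2-fold left 1186, 734, 546, 1122, 782 and 707 in that order, and 352, 197 and 156 shared in one direction by static and dynamic 3D, static 3D and fiber, and dynamic 3D and fiber, since a minimum fold removes smaller changes.

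Leaving out 1 library at a time gave 7319 to 9808, 5733 to 8762, 4503 to 7748, 6543 to 9355, 4571 to 8373 and 5014 to 7397 genes in the same order, each highest without dynamic 3D replicate 1. The shared calls ran from 3639 to 6169, 2582 to 4661 and 2366 to 4239. Called lists numbered 9 to 13, 11 to 12, 19 to 21, 9 to 11, 11 to 15 and 12 to 15.

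With a correlation estimated for each list, 3, 0, 2, 1, 1 and 3 lists were called by camera in the same order, in place of 9, 11, 19, 9, 11 and 13. With fry, which does not compare a list with other genes, 23, 23, 24, 26, 22 and 23 were called. Of 901 alternatives for the 72 called lists, 824 kept the call and 77 lost it, 62 of these with the estimated correlation, and none reversed. Of 5091 alternatives for 408 results of named genes, 5030 kept the side of the threshold, 15 of them with a change of sign and no call in either fit, 41 lost a call, 18 gained one and 2 reversed. Both reversals were in FOS without dynamic 3D replicate 1. FOS ran from -0.77 to 0.71 on the log2 scale for dynamic 3D against 2D and from -0.85 to 0.63 for fiber against dynamic 3D as 1 library was left out at a time, and was at 144 CPM in that replicate against 29.2 and 34.1 in the others.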

Other observations

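The tests of dynamic 3D replicate 1, the scaling test, the RBM3 value without that replicate, and the length tests for single systems were chosen after the results were seen, as was the choice of genes for a single system.

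Each culture system had genes that were called and at least 2-fold apart from each of the other 3. Static 3D had 225 such genes higher and 17 lower. Besides hypoxia-induced genes, IGFBP5, an IGF-binding protein, was at 31.2 ± 3.32 CPM in static 3D against 2.21 to 4.03 elsewhere, and EIF5, a translation initiation factor, was at 166 ± 5.68 against 341 to 451. Fiber had 47 genes higher and 64 lower. The transcription factor gene EBF2 was at 65.1 ± 4.32 CPM in fiber against 2.40 to 8.504, HPGD, which degrades prostaglandins, at 19.1 ± 1.66 against 4.23 to 6.01, and ANGPT1, an angiopoietin, at 12.2 ± 0.845 against 2.40 to 3.12. POU3F1, a neural POU factor, was at 6.10 ± 0.227 CPM in fiber against 17.7 to 23.1.

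Dynamic 3D had 61 genes higher and 26 lower than each other system. Higher genes included the p53 targets ZMAT3 (54.4 ± 21.8 CPM against 9.98 to 18.2) and EDA2R (28.4 ± 5.76 against 5.23 to 10.3), and INPP5D, a lipid phosphatase (35.3 ± 6.42 against 9.25 to 10.9). DDHD2, a lipase, was lower (12.8 ± 2.46 against 31.0 to 34.8). In 2D, 23 genes were higher and 74 lower than in each other system. SLC7A5 was at 253 ± 2.72 CPM in 2D against 53.2 to 87.2, ARHGAP23 at 41.4 ± 1.07 against 12.1 to 16.98, and DUSP8, a phosphatase of stress kinases, at 4.33 ± 0.488 against 16.99 to 27.3.

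Dynamic 3D replicate 1 stood apart from replicates 2 and 3, with higher p53 targets and immediate-early genes and lower NODAL and LEFTY1. Outside dynamic 3D no library lay more than 0.170 from the mean of its group, a mean that held the library itself. Replicate 1 lay 0.473 from the nearest other group, fiber, or 2.77 times as far, from a mean that did not hold it. These measures differ, and the ratio is too high by an amount not computed. The distance argues against a library like those measured from another system under this label, less strongly than the ratio reads. Replicate 1 lay 0.464 from the mean of replicates 2 and 3 (2.73 times as far, with the same limit), so distance does not favour its own label either. At 21 genes particular to replicates 2 and 3, its median position was 0.77 on a scale from the nearest other system (0) to those replicates (1), but the quartiles were 0.07 and 0.91. Component 3, with 18.4% of the variance, placed it with replicates 2 and 3 (-28.10 against -25.00 and -22.80), with fiber at -9.67 to -8.39. Component 1 placed it nearer to fiber (-14.71 against -21.63 to -19.98) than to replicates 2 and 3 (15.52 and 14.93). These values point both ways, and an unusual culture of another system stays open. In replicate 1, 58 genes stood more than 1.5-fold above every other library, where the next library had 7. This argues against a mixture of cells like those of replicates 2 and 3 with cells of another of the 4 systems. A mixture that holds dynamic 3D cells in another state was not covered by this test. A sample from outside these 12 libraries or a different state of that culture stays open too. RNA quality and library preparation were not tested as causes either. Of the RNA quality lists, histones stood at 0.796 relative to 2D in replicate 1 and at 0.261 and 0.220 in replicates 2 and 3. Ribosomal protein genes differed less, at -0.286 in replicate 1 and at -0.367 and -0.310 in replicates 2 and 3. No biological explanation was tested, because the labels name no difference between the replicates.

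Ribosomal protein and oxidative phosphorylation genes were lower in each 3D system than in 2D, with median log2 changes of -0.235, -0.277 and -0.252 in static 3D, dynamic 3D and fiber. By camera with an estimated correlation, neither list was called in any of these comparisons. The choice among 4 scalings does not account for this, since the median nearest to 0 over them and the 3 comparisons was -0.18. These scalings differ little (-0.241 to -0.179 in static 3D), so the test could hardly have come out otherwise. All are relative, and a change in total RNA per cell cannot be seen with them. Genes matched for transcript length and expression level showed 41.1% of the change in dynamic 3D (95% range of matched lists -0.159 to -0.051) and 34.7% in fiber (-0.119 to -0.048), which argues against these properties as the whole cause there. In static 3D they showed 62.5%, and the lists lay below the range of matched lists, whose lower end was -0.198. This goes against length and level as the whole cause. Whether they account for most of that change cannot be told apart from an effect of the culture system, since matched genes showed more of it than in the other systems. An effect of the culture system itself stays open and untested. The ribosomal protein list was written as an RNA quality list, and RNA quality was not tested as a cause. Reads assigned to no gene made up 12.5% in 2D, 13.7% in static 3D, 13.3% in dynamic 3D and 12.7% in fiber.

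RBM3, a cold-induced gene, was lower in dynamic 3D than in any other system. Replicate 1 alone is argued against as the cause, since RBM3 changed by -2.58 against 2D without it. A higher culture temperature predicted that CIRBP, another cold-induced gene, would be lower, and it changed by -0.93 (SE 0.066, 84.3 ± 8.21 against 160.8 ± 11 CPM), which is consistent with that explanation. The heat shock list was not called against 2D (camera adjusted p = 0.55), and static 3D also had less RBM3 (-0.49) and CIRBP (-0.42), where the heat shock list was lower. The labels give no temperature, and an effect of moving suspension other than temperature stays open.

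For each comparison the 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. In each case 1 split, the real one, gave as many genes. The real splits called 8419 genes for static 3D, 7000 for dynamic 3D and 5758 for fiber against 2D, 7723 for fiber against static 3D, 5898 for fiber against dynamic 3D and 6306 for dynamic against static 3D. The highest other split called 0 with edgeR, and at an unadjusted p under 0.05 it called 340, 2970, 353, 277, 2961 and 1693 genes in that order. Each other split mixes libraries of both systems, so real differences enter its spread. Its 0 calls are therefore no measure of what chance gives.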
